A study of Drosophila melanogaster with 3 samples.

How the data were processed

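RNA from unfertilized eggs of y w Drosophila melanogaster was extracted with Trizol and made into Illumina libraries, per the labels' protocols. The series holds 3 libraries with 1 library per group, namely rRNA-depleted total RNA, its polyA-plus fraction and its polyA-minus fraction. The genome build was dm3, per the submitters' processing notes. The aligner, the read counter, the rule by which sisRNAs were called and the treatment of reads that map to several places are not given in the sources used here. A sisRNA is a stable intronic sequence RNA, that is, an RNA made from an intron that persists after splicing.

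The authors deposited 2 sheets. The longer list names 295 host genes with their chromosome arm and with the poly(A) signal (PAS) hexamers found for each, which are aauaaa, auaaaa, auuaaa, combinations of these, or none. The counted list gives 140 sisRNAs with a host gene, the approximate dm3 coordinate of the sisRNA centre, the hexamers and a read count. The read counts are whole numbers that the authors deposited without normalization, and their single column names no library, so they were treated as 1 pooled value per sisRNA. The counts came with no replicate, no sisRNA length and no library total. The sum of 11169 reads over the counted list is therefore not the depth of a library, and a count per kilobase could not be formed. The sequence in which the hexamers were sought, and its length, are not given in the sources used here.

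The design fixed before the data were examined compared the 3 libraries. Those 5 planned results (polyA-minus against polyA-plus, each fraction against total, the count of features 2-fold apart and the rank agreement) need a value per library and were not computed. The lists were analysed as they stand instead. Exact Poisson 95% intervals were computed for each read count and exact Clopper-Pearson 95% intervals for each share, and both cover counting error only. Sequencing reads without molecular identifiers are not independent molecules, so these intervals understate the error. Medians over sisRNAs have order-statistic 95% intervals. A group's median read count was placed among the medians of 10000 random groups of as many sisRNAs, as a description of the list, and its percentile is given. Association between list membership and arm was tested by a chi-square statistic with 100000 permutations, and 2 by 2 tables by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment. Genes are not independent replicates in these tests.

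The rule for named genes, for a file with a single value column, took the 10 highest and the 5 lowest sisRNAs and each member of 11 gene lists that was present. The lists were known sisRNA hosts, germ plasm and axis genes, the piRNA pathway, maternal cell cycle and egg activation, RNA binding and splicing, transcription and chromatin, signalling and polarity, cytoskeleton and vesicles, RNAs chosen as polyA-minus controls, follicle cell genes, and zygotic genes. The rule and the lists were also fixed before the data were examined. Host symbols were matched to the gene names and synonyms of the Ensembl release 115 annotation of BDGP6.54 and the RefSeq table of gene synonyms. Of the 295 genes 288 matched, 2 of them on another arm than the one listed, and 137 of the 140 counted hosts matched. That annotation uses another build than dm3, so no coordinate was moved between them. It served only for names, gene and intron lengths and the order of genes along an arm.

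For comparisons of hosts with other genes the background was the 11740 protein-coding genes with an intron on the 5 main arms, of which 283 were hosts in the longer list. The test of the share of hosts per chromosome group set all 295 listed hosts against 11819 such genes, chromosome 4 included. Random sets of genes were drawn with as many genes per arm, or per arm and per 1 of 10 bins of longest intron length. Expression in eggs could not be used as a criterion, so genes that eggs do not express stayed in the background. The random-set and permutation steps were tested on simulated data. Among 200 random sets without an effect 4 were called for their share of genes near the centromere, and 100 of 100 sets with 20% of genes there were called, each with 283 genes. The permutation test of listing by arm called 13 of 200 simulations without an effect and 192 of 200 with 70% of X-linked and 40% of other genes listed, with 294 genes. Alternatives were a minimum of 10 or 20 reads, leaving out the highest sisRNA, sisRNAs marked with a cis-natural antisense transcript (cis-NAT) or those with 2 centres, other definitions of the part near the centromere, matching on gene length, and leaving out each arm. Computation used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.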

Results

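The data describe intronic RNAs in the unfertilized egg of Drosophila melanogaster, a cell whose RNA was laid down by the mother. Total RNA was sequenced after removal of ribosomal RNA, as were its polyadenylated and non-polyadenylated fractions, with 1 library each. The longer list named 295 host genes and the counted list gave 140 sisRNAs with 11169 reads in all. The read counts stood in 1 column that named no library, so the 3 fractions could not be set against each other, and no value has a replicate. The read depth of the libraries is unknown from these lists. A high count can reflect a long sisRNA as well as an abundant one, because no lengths were given.

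The first question was which introns left RNA in the egg and at what level. The read count per sisRNA ranged from 8 to 869, with a median of 48 (order-statistic 95% interval 40 to 61, n = 140 sisRNAs). The quartiles were 25.8 and 88.8 reads. The 10 highest sisRNAs held 3844 reads, 34.4% of all listed reads (exact 95% interval 33.5% to 35.3%), and 22 sisRNAs held 50% of them. At least 100 reads were listed for 29 sisRNAs, and 25 had under 20 reads.

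The highest count belonged to the sisRNA of CG11008 on arm 3L, centred at position 12808186 (all positions in dm3), with 869 reads (Poisson 95% interval 812 to 929). It was followed by that of RpL35A, a protein of the large ribosomal subunit, at 1292470 on 3R, with 638 reads (589 to 689). The intervals of these sisRNAs did not overlap each other or that of the third, in wal, the alpha subunit of electron transfer flavoprotein, with 454 reads (413 to 498) at 7577769 on 2R. Nipped-B, which loads cohesin onto chromosomes, followed with 383 reads (346 to 423) at 582231 on 2R. CG33217 had 325 reads (291 to 362) at 23123918 on 3L. The actin-binding protein gene coro, at 2759094 on 2R, had 275 reads (243 to 309), and tun, at 11737346 on 2R, had 265 (234 to 299), a difference within counting error. The nuclear pore gene gp210 had 222 reads (194 to 253) at 1649842 on 2R. CG2938, at 3829618 on X, had 212 reads (184 to 243). CG1399, annotated as LRR, had 201 reads (174 to 231) over 2 listed centres at 3567927 and 3569854 on 2R. The last 3 of these differed by less than counting error.

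At the other end of the list, Graf on X had 8 reads (3.45 to 15.8) centred at 15649047. CG9526 on 2L, botv on 2R and CG1753 on X, which is annotated as the cystathionine beta-synthase gene Cbs, had 9 reads each (4.12 to 17.1). Their centres lay at 6457162, 15017487 and 20916438. CG15445 on X had 11 reads (5.49 to 19.7) at 20988683. The intervals of these 5 sisRNAs overlapped, so their order was not resolved at this depth. The ratio of the highest to the lowest count was 109.

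Genes with known roles in the germ line and in RNA regulation were present among the hosts. From the 11 lists, 12 genes were in the longer list and 6 of these had a read count. The piRNA pathway gave 2 of its 13 genes, the Argonaute genes piwi and AGO3, where sets of genes matched for arm and longest intron held 0.40 on average and 552 of 10000 sets held as many. The sisRNA of piwi, centred at 10984705 on 2L, had 37 reads (26.1 to 51.0), and AGO3 had no read count. RNA binding and splicing gave 3 of 20 genes (mean of matched sets 1.01). These were Fmr1, a translational regulator, with 53 reads (39.7 to 69.3) at 5932728 on 3R, glo, an hnRNP gene, with 128 reads (107 to 152) over 2 centres at 7643364 and 7644076 on 3R, and the hnRNP gene sqd with no count. As many or more members were in 733 of 10000 matched sets. From the known sisRNA hosts 1 of 7 was listed, rga, which encodes the NOT2 subunit of the CCR4-NOT deadenylase, with 53 reads (39.7 to 69.3) at 1435138 on 3R. The germ plasm and axis genes gave 1 of 18, the RNA-binding protein gene BicC, with 28 reads (18.6 to 40.5) at 16045470 on 2L. The cytoskeleton and vesicle list gave 2 of 17, the myosin gene ck with 85 reads (67.9 to 105) at 15057349 on 2L and the kinesin light chain gene klc with no count.

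The cell cycle and egg activation list gave 1 of 16 genes (cycA, a mitotic cyclin), transcription and chromatin 1 of 18 (Trl, which encodes GAGA factor) and signalling and polarity 1 of 20 (sgg, the GSK3 kinase gene). None of these had a read count under its symbol. None of the 18 follicle cell genes, the 13 zygotic genes or the 12 polyA-minus controls was listed. The background of genes with an intron held 13 of the follicle cell genes and 9 of the zygotic genes, and matched sets had on average 0.18 and 0.24 of them, so their absence was not distinguishable from chance. Of the 12 polyA-minus controls 6 matched the annotation and the background held 1, so that list could not be compared. No list held more members than the upper end of the central 95% of the matched sets.

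The lists record whether a hexamer of the poly(A) signal, which directs cleavage and polyadenylation, was found for each entry. The searched sequences were not given, so the number expected by chance could not be formed, and whether the hexamers act is unknown. In the longer list 221 of 295 genes (74.9%) had at least 1 motif and 74 had none (25.1%, exact 95% interval 20.2% to 30.4%). The canonical aauaaa was listed for 137 genes (46.4%, 40.6% to 52.3%), auaaaa for 84 (28.5%, 23.4% to 34.0%) and auuaaa for 71 (24.1%, 19.3% to 29.4%). A single motif was listed for 156 genes, 2 motifs for 59 and all 3 for 6. The number of listed genes equalled the authors' tally in each of 6 chromosome groups, and the motif counts were not compared with a tally. In the counted list 44 of 140 sisRNAs had no motif (31.4%, 23.9% to 39.8%). Motifs were identical in both lists for 136 of 137 shared genes. The exception was CG5899, with auaaaa in the longer list and none in the counted list.

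**Figure D1:**
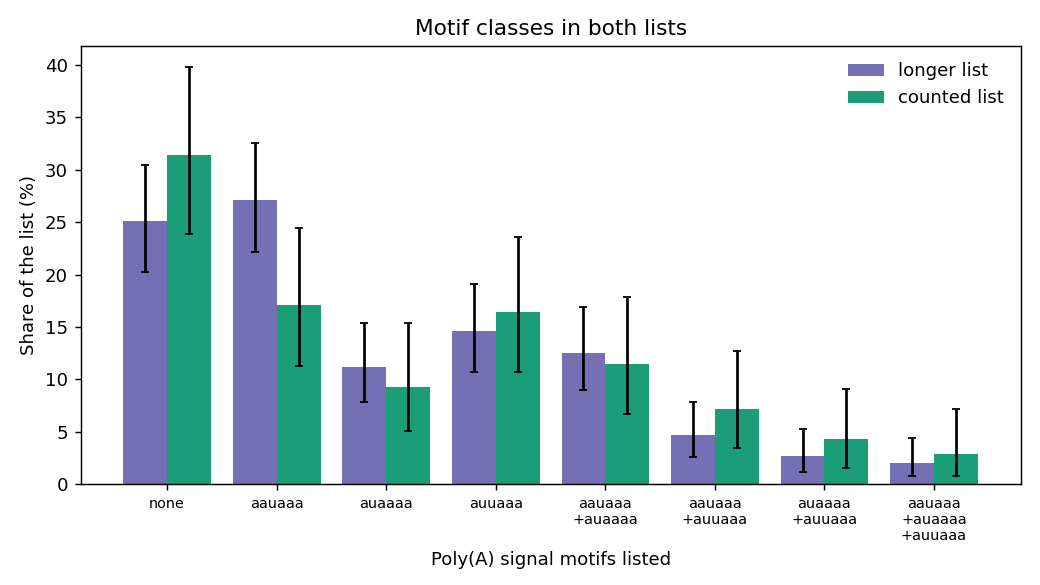
Share of each list (vertical axis, percent) in each class of poly(A) signal motifs (horizontal axis), with exact 95% intervals as bars, for the 295 genes of the longer list and the 140 sisRNAs of the counted list. Genes with aauaaa alone made up 27.1% of the longer list and 17.1% of the counted list.

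The counted sisRNAs were then compared by motif. The 44 sisRNAs without a motif had a median of 36 reads (27 to 56), and the 96 with a motif had 53 (44 to 70). Among the sisRNAs without a motif the highest were CG2938 with 212 reads and glo with 128. The log2 ratio of the medians was 0.56, with a bootstrap 95% interval of -0.09 to 1.20 that includes 0. The median of the group without a motif lay at percentile 1.43 of random groups of 44. It moved to percentile 6.40 without arm 2R and to 14.2 with a minimum of 20 reads, inside the central 95% of random groups. Medians were 51.5 reads (41 to 69) with aauaaa, 55 (39 to 94) with auaaaa and 52 (42 to 85) with auuaaa, and each lay inside the central 95%.

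By chromosome, the highest counts concentrated on arm 2R. Its 22 sisRNAs had a median of 86 reads (48 to 201), at percentile 99.7 of random groups of 22, and 6 of the 10 highest sisRNAs lay there (wal, Nipped-B, coro, tun, gp210 and CG1399). The medians were 41 reads on 2L (28 to 64, n = 19), 54.5 on 3L (27 to 93, n = 20), 47 on 3R (27 to 56, n = 37) and 44 on X (35 to 74, n = 42). Of 12 groups examined by motif, arm and cis-NAT mark, 2 lay outside the central 95% of random groups, the group without a motif and arm 2R. No correction for the 12 groups was applied, and the groups were not part of the design fixed before the data were examined.

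The 13 sisRNAs marked by the authors with a cis-NAT, a transcript from the opposite strand of the same place, had a median of 47 reads (15 to 56) against 52 for the other 127. The percentile was 39.8. Of these sisRNAs 6 had hosts with no remark in the longer list and 1, CG1091, was marked AS there, as were 6 other genes of that list, so the group depends on which list is used. Whether reads were counted by strand is not given in the sources used here, so reads of an overlapping antisense transcript cannot be told apart. The centres of 4 pairs of sisRNAs lay within 5000 bases of each other. CG1091 (27 reads) and alphaTub84B (72 reads) were 1248 bases apart on 3R, and Mgstl (44 reads) and CG1753 (9 reads) 1992 bases apart on X. CG12384 (85 reads) and san (17 reads) were 2579 bases apart on 2R, and RpL35A (638 reads) and snr1 (31 reads) 4748 bases apart on 3R.

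**Figure D2:**
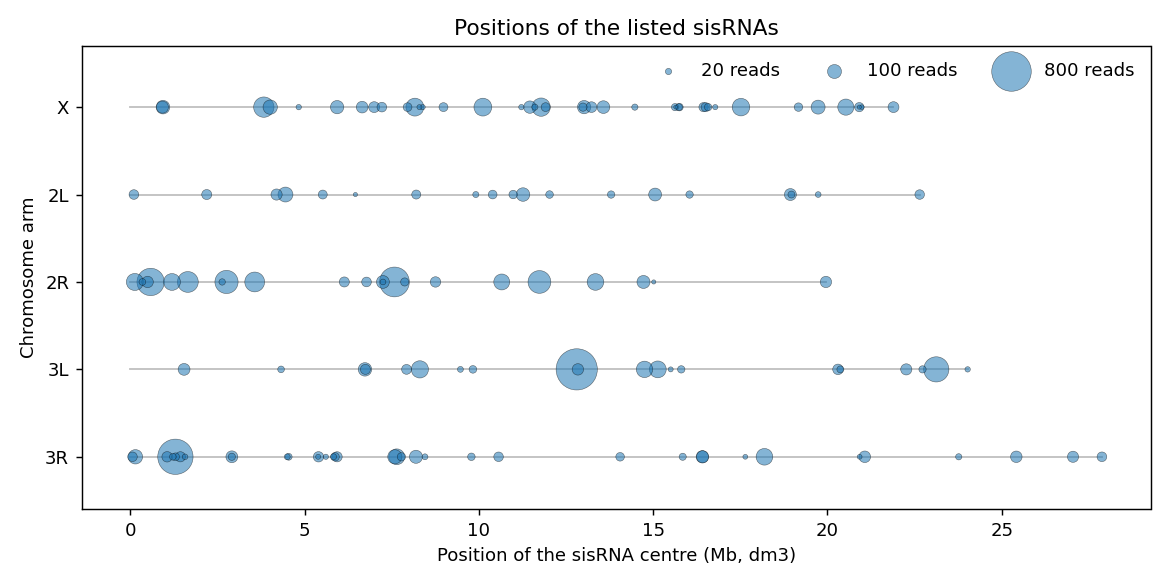
Centre of each listed sisRNA (horizontal axis, Mb in dm3) on the arms X, 2L, 2R, 3L and 3R (vertical axis), with the area of a point proportional to its read count. Points with 2 listed centres are drawn at the first, lines end at the last listed centre, and CG2893, placed by the authors on the separate dm3 sequence XHet, is left out. The large points on 2R include Nipped-B (383 reads) at 582231 and gp210 (222 reads) at 1649842.

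The counted list held 137 of the 295 genes of the longer list (46.4%, 40.6% to 52.3%). It also held 3 hosts whose symbols were not in the longer list, corp with 164 reads, CG33260 with 138 and syb with 52. They were chosen for mention after their values were seen. The lists were compared by symbol, so a sisRNA listed under another gene name in each would pass as uncounted. The share that was counted differed by arm. It was 63.1% on X (41 of 65, 50.2% to 74.7%) and 58.7% on 3R (37 of 63, 45.6% to 71.0%), against 39.6% on 2L (19 of 48), 36.2% on 2R (21 of 58) and 31.7% on 3L (19 of 60). The permutation p over these 5 arms was 0.00056 (0.00112 after Benjamini-Hochberg adjustment over 2 tests). Of the genes without a motif 43 of 74 were counted (58.1%), against 94 of 221 with any motif (42.5%). The share among genes with a motif was not uniform, with 24 of 80 genes with aauaaa alone (30.0%, 20.3% to 41.3%) and 42 of 71 with auuaaa, alone or with others (59.2%, 46.8% to 70.7%). The odds ratio of no motif to any motif was 1.87 (95% interval 1.06 to 3.32, Fisher's exact p = 0.0224, adjusted p = 0.0224). Neither of these 2 tests was part of the design fixed before the data were examined, and the adjustment covers only them. This comparison by motif was not made within arms, so it is not separated from the difference by arm. The rule that took genes from the longer to the counted list is not given in the sources used here.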

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

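All alternatives in this part were chosen after the data were seen. The alternatives fixed before the data were examined concerned ratios between libraries (library scale, pseudocount, size rule), which need a value per library, and were not run. Keeping 1 feature per host gene changed nothing, since each host was listed once. No paired analysis was possible because each group held 1 library and no value was tied to a library. The median read count, the number of sisRNAs with at least 100 reads and the log2 ratio between sisRNAs with and without a motif stayed within their errors, or within 1.5 times for the number, under each of the 5 alternatives. The share of reads in the 10 highest sisRNAs moved from 34.4% to 35.6% with a minimum of 20 reads and to 30.6% without CG11008. It was 36.4% without the sisRNAs marked with a cis-NAT and 35.6% without those with 2 centres. Each shift exceeds the counting error of the share and follows from taking sisRNAs out of the total or out of the 10 highest. The share without a motif was 31.4% in the counted list against 25.1% in the longer list. The low median of sisRNAs without a motif lost its place outside the central 95% of random groups without arm 2R (percentile 6.40) and with a minimum of 20 reads (percentile 14.2), and the cause was not tested. The percentile of arm 2R stayed outside under 6 of 6 alternatives, which kept 19 to 22 of its sisRNAs. Of the 21 counted hosts on 2R placed in the gene order, 8 were among the 10% of genes nearest the centromere. Among these 8 were Nipped-B, coro and gp210, and the median of 2R without the 8 was not computed. For the 25 sisRNAs with under 20 reads the counting intervals are wide, and what sets the low end of the list was not tested.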

Other observations

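The tests of host position against chance and with the nearest 5% or 20% of genes, of listing by arm against chance and without each arm, of gene and intron length, of the X share and of 4 added gene groups were chosen only after the data had been seen. The tests of position matched for intron length, of reads near centromeres, of listing within motif class or intron length and of motif pairs had a prediction written before their result was seen.

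The host genes were long genes with long introns, though the intron that holds each sisRNA was not located. In the BDGP6 annotation the median longest intron of the 283 hosts was 1988 bases, against 248 for the 11740 protein-coding genes with an intron. The median of hosts lay above every one of 10000 random sets (central 95% 171 to 384 bases). Median gene length was 6668 bases against 2559, and the median number of distinct introns was 7 against 3. The chance that a gene is listed may itself rise with the length and number of its introns. The rule by which sisRNAs were called is not given, so these comparisons cannot separate a property of hosts from ease of detection. For the 137 counted hosts the median longest intron was 1120 bases, and the difference from the whole list was not tested. A further departure was the X chromosome, with 65 of the 295 listed hosts (22.0%, 17.4% to 27.2%) against 15.9% of 11819 genes on the main arms and chromosome 4 (Fisher's exact p = 0.00473, adjusted over 6 chromosome groups 0.0284). The other groups had adjusted p between 0.459 and 0.725. With only the 283 hosts in the background of 11740 genes, 22.6% of hosts were on X (adjusted over 5 arms 0.0154). The X share was not compared with sets matched for intron length, and the background includes genes that eggs do not express.

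Several hosts belonged to the same complex or pathway, noticed when the list was read. CCR4-NOT, which shortens poly(A) tails, had 3 of 9 subunit genes (rga, l(2)NC136 and twin), where sets matched for arm and longest intron held 0.26 on average (percentile 99.96). Small RNA pathway proteins had 6 of 25 (piwi, AGO3, loqs, vig, Tudor-SN and Fmr1, mean of sets 0.84, percentile 99.98), of which 2 are also in the piRNA list fixed earlier. Cohesin and condensin factors had 4 of 18 (Nipped-B, san, cap-G and cap-H2, mean of sets 0.36, percentile 99.99). These 3 groups were picked because their members had been seen in the list, so the percentiles cannot show an excess, and none of the lists fixed beforehand showed one. Cytosolic ribosomal proteins, with RpS27, RpL35A and RpS15Aa among 85 genes, were at percentile 71.4 and show none.

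Many counted sisRNAs lay near centromeres, among them those of Nipped-B, gp210 and CG33217. Of the 283 hosts, 51 (18.0%) were among the 10% of genes nearest the centromere of their arm, a larger share than in every one of 10000 random sets (percentile 100, central 95% 6.71% to 13.4%). By arm the share was 14 of 56 hosts on 2R (95% interval 14.4% to 38.4%), 22.6% on 3R (12.9% to 35.0%), 16.1% on 3L (7.62% to 28.3%), 13.3% on 2L (5.05% to 26.8%) and 12.5% on X (5.55% to 23.2%), and the last 3 intervals include 10%. Sets matched for longest intron gave percentile 99.97 for all hosts and 99.98 for the counted hosts alone. This argues against intron length, as matched in 10 bins, as the whole cause for the counted hosts. Lengths can still differ inside a bin, so the longest introns were matched only coarsely. The position was also noticed on these same genes. Whether counted and uncounted hosts differ in position was not tested. For all hosts the call depended on the part of the arm taken and on the matching. With the nearest 5% of genes the share was 12.4%, above the range matched for longest intron of 3.89% to 9.19%. With the nearest 20% of genes the share of 26.1% fell inside the range matched for longest intron of 17.3% to 26.5%. It lay above that of sets matched for gene length (16.6% to 25.8%). The 148 hosts without a read count had 14.2% among the nearest 10% of genes, inside the random range (percentile 95.16, and 80.24 when matched for intron length). Among the 5% of genes nearest the centromere these hosts had 10.1%, above the random range of 2.03% to 8.78%, but inside that of sets matched for intron length (3.38% to 11.5%). For those genes the call against chance thus depends on the part of the arm taken, and intron length stays open. Reads shared between the repeats common near centromeres could contribute. The median of the 30 counted sisRNAs with hosts in the nearest 10% was 54.5 reads against 48 for the other 107 (percentile 72.99), which does not decide it, and no biological explanation was tested.

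The counted share of the longer list differed by arm with a permutation p of 0.00056. Permuting within motif class gave 0.00039 and permuting within 5 bins of longest intron 0.00312, which argues against either property as the whole cause. Leaving out each arm gave p between 0.00027 and 0.0129, the highest without X. A candidate explanation that stays open is that the selection of sisRNAs for counting was made differently along the chromosomes, which these lists cannot test.

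The motifs aauaaa and auuaaa were listed together for 20 genes, where independence gives 33.0 (odds ratio 0.36, 95% interval 0.19 to 0.66, Fisher's exact p = 0.000383, adjusted over 3 pairs 0.00115). Longer searched sequences alone would raise each pair, so they do not account for the value of this pair. Whether they contribute to multiple motifs in general cannot be decided, because the searched lengths are not given. The pair aauaaa and auaaaa was listed for 43 genes against 39.0 (odds ratio 1.30, 0.76 to 2.24), and auaaaa and auuaaa for 14 against 20.2 (0.54, 0.26 to 1.07). The intervals of the pairs with aauaaa did not overlap, as predicted if aauaaa and auaaaa share bases in aauaaaa. The interval of aauaaa with auaaaa includes an odds ratio of 1, so no excess of that pair was resolved. The separation rests on the low odds ratio of aauaaa with auuaaa and does not decide the hypothesis, which needs the sequences to test. It leaves the low number of genes with both aauaaa and auuaaa without an account.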
